A study of Triticum aestivum with 122 samples.

How the data were processed

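RNA was measured by sequencing of poly(A)-selected libraries from the unemerged heads of bread wheat (Triticum aestivum) cultivar Vida. Seeds germinated for 48 h with 1 µM of the brassinosteroid 2,4-epibrassinolide (EBR) or with 1 µM of dimethyl sulfoxide (DMSO), the control. Plants grew at 22 °C with 16 h of light, and at the tetrad stage part of the pots of each seed treatment went to constant 29 °C. Heads were taken before the move (0 h) and 8, 16 and 24 h after it, and each head was split into floret and rachis, the axis that carries the spikelets. The labels give 32 groups of tissue, seed treatment, temperature and time, and they call the samples biological replicates. The groups named 29 °C at 0 h hold heads of pots that had not yet been moved.

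The submitters' processing notes name FastQC, MultiQC, Trimmomatic 0.36, STAR, featureCounts and DESeq2, without saying what each was used for, and the genome build is not given in the sources used here. The authors deposited a table of signal per gene and library, named normalized counts, and all libraries share it. Each library's values were tested for being whole reads divided by a single factor: 100% of the values in every library were whole within 0.01 after this factor was removed. As read here, the table holds 55578 entries, of which 1 was incomplete and left out, so that 55577 entries of 53798 gene IDs were used. These entries cover chromosomes 1 to 4 and part of 5. Whether the table of the authors extends further is not known here. Chromosomes 6 and 7 were not analysed. Of 122 samples 121 have a column in the table (61 floret and 60 rachis libraries), and the remaining sample (rachis, EBR seed, 22 °C, 8 h, replicate 1) entered no test.

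Values were analysed as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in the variance, and a spread shared by all groups of the tissue. Genes entered with a value of at least 10 in at least 3 libraries of the fit, which left 38320 genes in the floret, 38883 in the rachis and 40613 in the joint fit of both tissues. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale, with their standard error (SE). The comparisons were heat (29 °C minus 22 °C) at each time and seed treatment, the EBR by heat interaction over the 3 heated times, EBR minus DMSO in any condition, at 0 h and as means of 8, 16 and 24 h at each temperature, pots to be moved minus pots kept at 0 h, time at 22 °C, floret minus rachis in DMSO heads at 22 °C and 0 h, and the tissue by heat interaction. Groups, tests, filters, alternatives and the rule for naming genes were fixed before the data were examined. Heat comparisons at different times or seed treatments share no library, but floret and rachis come from the same heads and are not independent.

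Gene lists, cell type marker lists and promoter motifs had also been fixed, but 0 of the gene IDs matched any of the 155467 entries of the gene name table used here. No gene symbol, function, pathway, cell type marker or motif could be assigned, and genes appear by ID, whose first part gives the chromosome. The rule for genes without a description named up to 2 genes that rose and 2 that fell per comparison, with the largest fold change among those called with a mean of at least 50 and, for heat, with no overlap between the groups. The few IDs printed are a part of those the rule names and were chosen after their values were seen; some others were dropped after single libraries of theirs had been found far from the rest of their group. Single called genes printed beside a count of 1 fall outside the rule and were also chosen after their values were seen.

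Alternatives fixed in advance were pseudocounts of 0.5 and 5, no filter on low values, a stricter filter (mean of at least 50), rescaling by trimmed mean of M-values (TMM) factors, a fit of only the compared groups, edgeR 4.0.16 quasi-likelihood tests on the whole reads, leaving out each replicate number, and a replicate block. Alternatives added after seeing the data left out 3 plants, left out a set of co-varying genes, or used a plant's score on the main axis of variation as a covariate. Replicate numbers were checked for pairing: residuals of libraries with the same number had a mean correlation of 0.001 in the floret and 0.01 in the rachis, so no test within a tissue was paired. Floret and rachis of the same plant come from the same head and deviated together (mean correlation 0.25 in 56 plants, over 0.1 in 46 of them), so for the 2 tests between tissues the replicate block is the plant; their main fits have no block. Scores of single libraries were compared by permutation tests, exact for comparisons at a single time and with 100000 draws for means over 3 times and for correlations. The tests were also tested on simulated data: of genes changed 2-fold in simulated libraries like those of heat at 8 h after DMSO seed, limma called 77.6% in the floret and 47.8% in the rachis, and of genes changed 4-fold 100% in each. All changed genes had a mean of at least 50. Genes were simulated independently of each other, without the main axis of variation, so these shares do not hold for genes of lower level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.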

Results

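Transcripts were measured in 61 floret and 60 rachis libraries from wheat heads at the tetrad stage. Of the 32 groups, 26 held 4 libraries, 5 held 3 and 1 held 2. Each library held 14.5 to 21.8 M whole reads over the listed genes in the floret (median 17.4 M) and 10.6 to 18.2 M in the rachis (median 14.7 M). The table as read here covers part of the genome, so these are not full library depths. Between 41049 and 47131 genes had a value above 0 in a library, and the 10 most abundant genes took at most 3.64% of a library's values. Among 172 pairs of replicates the lowest chi-square per gene was 2.92, so no pair differed by as little as sampling noise.

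The largest axis of expression differences between heads of the same group is called the head axis here. It held 29.4% of the variation within groups in the floret and 29.9% in the rachis, against 8.69% and 6.21% for the next axis. The floret and the rachis of a plant had nearly the same place on it, as deviations from their group means (56 plants, Pearson r = 0.934, Spearman rho = 0.931, each with a permutation p of 1e-05, the smallest that the permutations can give; r = 0.911 without the 2 plants farthest from the median). It was the only relation of this kind computed, apart from the rank version. The floret mean of the head axis score was 0.99 in DMSO heads after 24 h at 29 °C (n = 4), 0.44 in those kept at 22 °C (n = 4), 0.25 in EBR heads after 8 h at 29 °C (n = 4) and -0.56 in those kept at 22 °C (n = 3). The sign of the score was set so that libraries with more genes above 0 at equal depth score higher. The first of these groups had a mean of 44748 such genes and the last 40439.

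**Figure D1:**
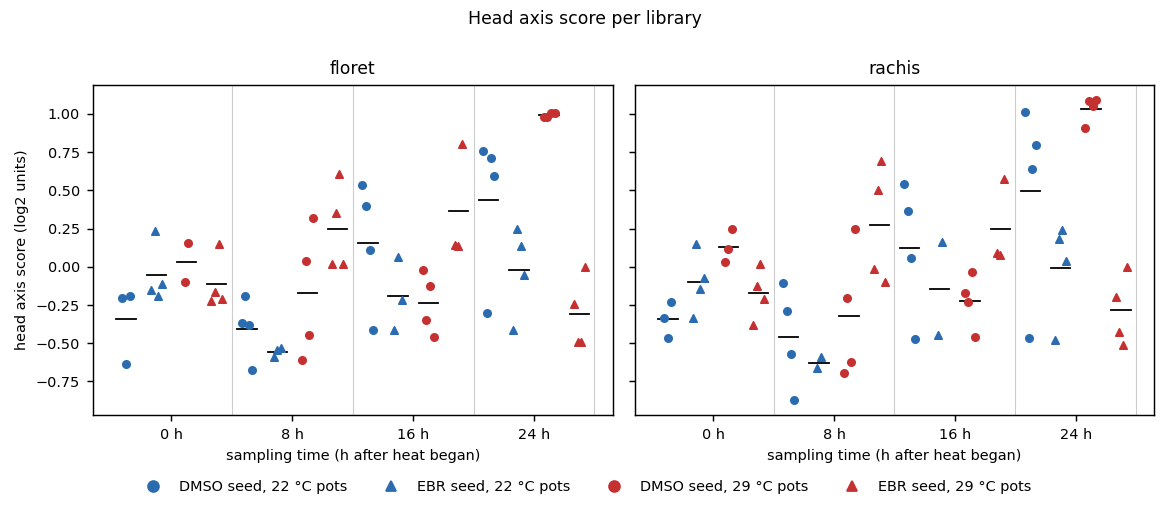
Head axis score (log2 units) of each library, by sampling time, seed treatment and pot temperature, in floret and rachis; points are libraries and bars are group means. In the floret the DMSO heads at 29 °C and 24 h have a mean of 0.99 and the EBR heads at 22 °C and 8 h a mean of -0.56.

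Heat after DMSO treatment of the seed addresses how the head responds to 29 °C without the brassinosteroid. At 8 h, 738 genes were higher and 940 lower in the floret, and 427 were higher and 327 lower in the rachis. At 16 h the floret had 937 higher and 1016 lower genes and the rachis 430 and 379. At 24 h far more genes differed: 8038 were higher and 6734 lower in the floret, and 6158 were higher and 5640 lower in the rachis. Genes changed at least 2-fold numbered 336 at 8 h and 5589 at 24 h in the floret, and 4043 of the latter were higher. Where floret and rachis both called a gene they went the same way in 434 of 434 genes at 8 h, 464 of 464 at 16 h and 6972 of 7053 at 24 h. The split into higher and lower genes depended on the scaling and the test. At 24 h edgeR called 6256 higher and 8005 lower genes in the floret and 4862 and 6743 in the rachis, and TMM factors gave 7142 and 7640, and 5385 and 6336. At 16 h in the floret TMM factors gave 1040 higher and 858 lower genes and edgeR 1180 and 1007, and at 8 h edgeR gave 748 and 735. In each of the 6 comparisons after DMSO seed the majority turned under at least 1 of the alternatives. With only the compared groups fitted the counts fell to 531 at 8 h in the floret and to 36, 219 and 1953 in the rachis. Leaving out each replicate number in turn gave 510 to 1299 genes at 8 h, 253 to 1593 at 16 h and 6923 to 15215 at 24 h in the floret, and 201 to 510, 142 to 755 and 3775 to 14022 in the rachis.

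TraesCS1B03G0819300.1, on chromosome 1B, was among the most strongly raised genes at 8 h. Its floret mean was 4049 ± 396 normalized counts (SD, n = 4) at 29 °C against 691 ± 115 (SD, n = 4) at 22 °C, a log2 fold change of 2.56 (SE 0.458, adjusted p = 3.2e-04). In the rachis it had 2260 ± 825 (SD, n = 4) against 286 ± 102 (SD, n = 4), a log2 fold change of 2.98 (SE 0.536, adjusted p = 6.2e-04). TraesCS4B03G0736800.2, on chromosome 4B, was called higher in all 6 heat comparisons of each tissue. At 16 h after DMSO seed its floret mean was 133 ± 10.8 (SD, n = 4) against 18.2 ± 6.22 (SD, n = 4), a log2 fold change of 2.85 (SE 0.357, adjusted p = 6.8e-07). Its call at 16 h after EBR seed in the rachis ended with only the compared groups fitted (adjusted p 4.0e-07 to 4.0e-01 over the alternatives). TraesCS2D03G0784200.1, on chromosome 2D, was nearly silent except in DMSO heads after 24 h at 29 °C, with group means of at most 4.19 elsewhere. There its floret mean was 1436 ± 502 (SD, n = 4) against 1.11 ± 1.12 (SD, n = 4) at 22 °C, a log2 fold change of 9.50 (SE 0.605, adjusted p = 8.8e-18) that ranged from 7.83 to 10.10 over the alternatives, since values near 0 make it depend on the pseudocount. In EBR heads at 29 °C and 24 h its floret mean was 0.44 ± 0.88 (SD, n = 4), and the rachis of DMSO heads at 29 °C and 24 h had 233 ± 259 (SD, n = 4).

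**Figure D2:**
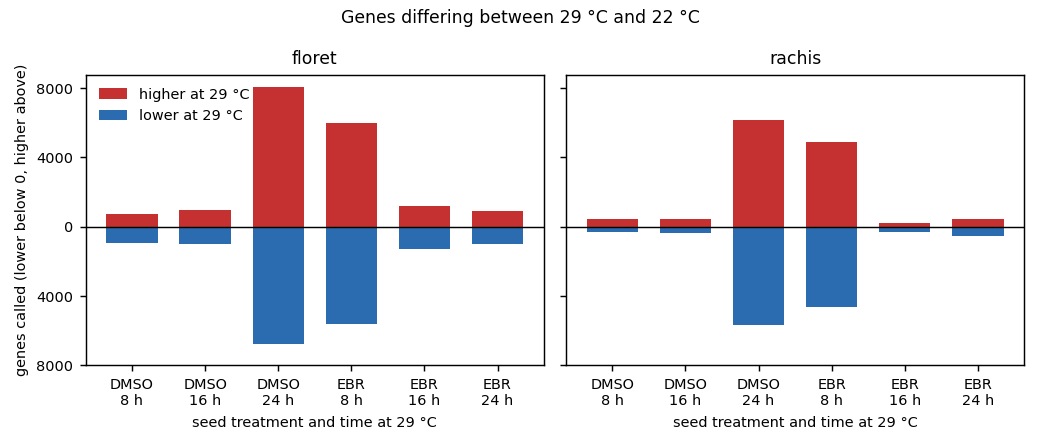
Genes called higher (above 0) or lower (below 0) at 29 °C than at 22 °C, by seed treatment and time, in floret and rachis. Heat at 24 h after DMSO seed and at 8 h after EBR seed stand above the other times, with 14772 and 11564 genes in the floret.

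Heat after EBR treatment of the seed asks the same of plants that received the brassinosteroid. At 8 h 5954 genes were higher and 5610 lower in the floret, and 4880 were higher and 4629 lower in the rachis, where the 22 °C group held 2 libraries. At 16 h the floret had 1194 higher and 1300 lower genes and the rachis 226 and 286. At 24 h the floret had 884 higher and 993 lower genes and the rachis 474 and 542. Genes called in both tissues went the same way in 6431 of 6432 genes at 8 h, 308 of 308 at 16 h and 573 of 573 at 24 h. The split again turned with the scaling or the test. At 24 h TMM factors gave 1057 higher and 770 lower genes in the floret and 498 and 439 in the rachis, and edgeR gave 1024 and 727 in the floret. At 16 h in the floret edgeR gave 1795 and 1465, and at 8 h in the rachis TMM factors gave 4594 and 4936. In each of the 6 comparisons after EBR seed the majority turned under at least 1 of the alternatives, among them runs without single replicate numbers, as at 16 h in the floret without replicate 1 (714 and 640) and at 24 h in the rachis without replicate 4 (274 and 211). With only the compared groups fitted, the floret had 60 genes at 16 h and 1116 at 24 h, and the rachis had 5578 at 8 h and 634 at 24 h. For heat at 16 h, EBR seed, rachis limma then called 0 (4047 at an unadjusted p under 0.05), and edgeR on all groups called 482. Leaving out replicate numbers gave 5914 to 10864, 591 to 1746 and 581 to 1176 genes at 8, 16 and 24 h in the floret, and 242 to 11684, 57 to 811 and 192 to 680 in the rachis. With a plant's head axis score in the other tissue as covariate, the 8 h count was 1217 in the floret and 828 in the rachis (8483 and 9780 in the same plants without it), and the 24 h count of DMSO heads was 11168 and 8958 (15380 and 11887). The covariate raised other counts. At 8 h DMSO heads then had 3286 floret and 1735 rachis genes (2056 and 796 without it), more than EBR heads. At 16 h after EBR seed the rachis had 855 (308 without it).

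TraesCS5A03G0211100.1, on chromosome 5A, rose at 8 h after EBR seed, though less than the genes that the rule named for that floret comparison (log2 fold changes of 7.87 and 7.85). It had 9381 ± 1592 normalized counts (SD, n = 4) in the floret at 29 °C against 115 ± 25.4 (SD, n = 3) at 22 °C, a log2 fold change of 6.35. In the rachis its mean was 28340 ± 7850 (SD, n = 4) and its log2 fold change 6.75. In DMSO heads at 8 h the rachis fold was 2.80 (adjusted p = 1.1e-03, and 1.8e-05 to 2.2e-01 over the alternatives); the call ended with only the compared groups fitted and without replicate 4. TraesCS2B03G0442100.1 and TraesCS2D03G0341300.1, on chromosomes 2B and 2D, fell at 24 h after EBR seed in both tissues. The former had a floret mean of 84.3 ± 25.7 (SD, n = 4) against 1352 ± 975 (SD, n = 4), a log2 fold change of -3.62 (SE 0.879, adjusted p = 8.5e-03), and the latter a log2 fold change of -3.58 (SE 0.849, adjusted p = 6.9e-03). In the rachis they changed by -3.72 and -3.50. Without replicate 2, 3 or 4 neither call remained in either tissue, with adjusted p from 9.1e-07 to 1.5e-01 over the alternatives for the former in the floret and from 3.6e-07 to 1.2e-01 for the latter.

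A small group of genes responded to heat alike at every time. After DMSO seed 110 genes were higher and 93 lower at all 3 times in the floret, where 3.8 and 4.4 would be shared by chance, and in the rachis 77 were higher and 52 lower. After EBR seed the floret had 178 higher and 238 lower genes and the rachis 53 and 60. In the floret 71 genes were higher and 54 lower in all 6 heat comparisons, and 31 were higher and 15 lower in all 12 comparisons of both tissues. The 31 lay on 14 chromosomes, with a median log2 fold change of 0.68, and the 15 on 11 chromosomes, with a median of -0.70. TraesCS4B03G0736800.2 was among the 31. The 110 genes defined in DMSO heads were higher in EBR heads in 110, 109 and 110 cases at 8, 16 and 24 h, with 98, 85 and 88 called, and the 93 lower genes were lower in 93, 93 and 92. With only the compared groups fitted 6 genes were higher and 4 lower in all 6 floret comparisons and 0 in all 12, and leaving out replicate numbers gave 3 to 19 higher and 6 to 11 lower genes in all 12.

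A heat score took the mean of the genes raised in every comparison of the other tissue minus the mean of those lowered there. Although the tissues share heads, genes from the other tissue separated every heated library from every other library. In the floret heated libraries lay between 0.978 and 1.42 and all others between -0.556 and 0.042. In the rachis the ranges were 0.197 to 0.82 and -1.08 to -0.30. The 0 h libraries of pots that were later moved lay with the unheated ones, with floret means of -0.267 (DMSO, n = 3) and -0.252 (EBR, n = 4).

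**Figure D3:**
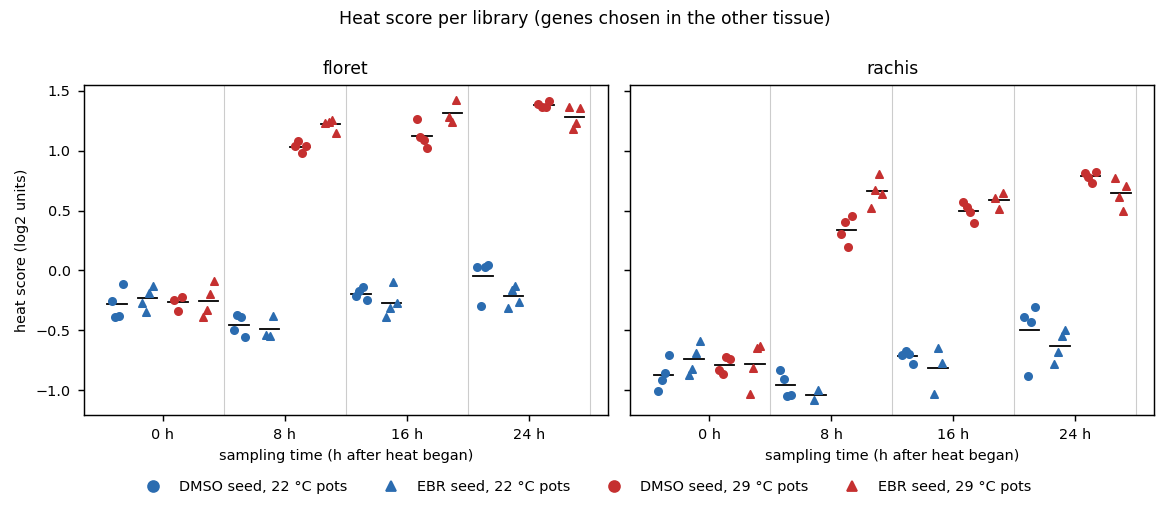
Heat score (log2 units) of each library from genes chosen in the other tissue, by sampling time, seed treatment and pot temperature; points are libraries and bars are group means. Every library taken after the move to 29 °C lies above every other library of its tissue, from 0.978 in the floret and from 0.197 in the rachis.

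The EBR by heat interaction asks whether the seed treatment changed the response to heat. The response differed between EBR and DMSO heads in 11896 genes in the floret and 9262 in the rachis. By time, it differed in 11235 floret and 7371 rachis genes at 24 h, in 8 and 5 at 8 h and in 190 in the floret at 16 h; in the rachis at 16 h limma called 0 (6768 at an unadjusted p under 0.05) and edgeR 32. The EBR by heat interaction at 16 h, floret, ranged from 0 to 1062 genes over the alternatives, with 0 in each of 3 of the 4 runs that left out a replicate number. At 24 h the heat effect was larger, or less negative, in EBR heads for 4697 floret genes and the reverse for 6538. The count moved with single replicate numbers, from 1551 without replicate 2 to 11410 without replicate 4 in the floret and from 348 without replicate 3 to 12629 without replicate 4 in the rachis. With the head axis as covariate it was 2773 for the EBR by heat interaction, floret, and 1275 for the EBR by heat interaction, rachis, against 12410 and 7608 in the same plants without it.

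EBR against DMSO addresses whether a treatment at germination still shows in the head. A joint test over the 8 conditions called 22557 floret and 20763 rachis genes. With the head axis as covariate it called 7512 and 3650, against 22363 and 20028 in the same plants without it. Leaving out replicate numbers gave 16728 to 19730 in the floret. Tested alone, which can call more genes than the joint test, 29 °C and 24 h gave 25075 floret genes (11137 higher, 13938 lower) and 23554 rachis genes. Leaving out replicate numbers gave 21785 to 23563 for EBR vs DMSO at 29C, 24 h, floret, and 19438 to 22415 for EBR vs DMSO at 29C, 24 h, rachis; with the head axis as covariate the counts were 11500 and 7133, against 25461 and 23792 in the same plants without it. As a mean of 8, 16 and 24 h at 29 °C, 357 genes were higher and 1251 lower with EBR in the floret, and 706 were higher and 1418 lower in the rachis. TraesCS5A03G0211100.1 was among the higher genes, by 1.20 in the floret (SE 0.295, adjusted p = 1.0e-02) and by 1.55 in the rachis (SE 0.31, adjusted p = 1.1e-03); the floret call ended without replicate 3 or 4, with adjusted p from 1.2e-06 to 7.9e-02 over the alternatives. The excess of lower genes at 29 °C depended on the test, with 403 higher and 401 lower genes by edgeR in the floret and 727 and 716 in the rachis, and 675 and 1024 after TMM scaling in the floret; with the head axis as covariate there were 1663 and 2182 for EBR at 29C, floret, and 1874 and 2112 for EBR at 29C, rachis. Without single replicate numbers the counts at 29 °C ranged from 290 to 3813 in the floret and from 278 to 1411 in the rachis. As a mean of the same times at 22 °C, 188 genes were higher and 212 lower in the floret, with 0 to 355 called without single replicate numbers and 2657 without the 3 plants named under the tissue comparison. In the rachis the only gene called at 22 °C was TraesCS3B03G1122300.1, lower with EBR by a log2 fold change of -0.95 (SE 0.155, adjusted p = 6.6e-03); 9449 genes had an unadjusted p under 0.05, and leaving out replicate numbers gave 0 to 65.

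Before any heat, 151 floret genes were higher and 34 lower in heads from EBR seed. Of the 151, 39 belonged to a set of 41 genes that rise and fall together across the floret libraries. The set was built from genes that correlated (Pearson r above 0.8) with the mean of low-numbered genes of chromosome 1A. Among these are TraesCS1A03G0002800.1 and TraesCS1A03G0001400.1, with log2 fold changes of 4.14 and 4.08 with EBR at 0 h. The 0 h libraries were also used, so the 39 and the share on chromosome 1A are in part built in. The set holds 17 genes on chromosome 1A and 8 on chromosome 1B. The mean of the 26 of them that also rise and fall together in the rachis lay above 5 on the log2 scale in 27 of 27 floret libraries of the plants numbered 10 to 16 and in 4 of 34 of those numbered 1 to 9. In the rachis it did so in 0 of 26 and 3 of 34. These 3 rachis libraries lay at 7.112, 7.622 and 8.08, and no other rachis library lay above 4.693. The correlation that picked the 26 genes in the rachis can thus rest largely on these 3 libraries. Each plant number is a single combination of seed treatment, temperature and time, so number and condition cannot be separated. Libraries of the same number are not independent evidence on the number. The cut between plants 9 and 10 was chosen after the values had been seen. The 112 genes outside the set had a median log2 fold change of 0.67. Without the set 98 genes were called, without those 3 plants 95, and without single replicate numbers 73 to 209. In the rachis 5 genes were higher and 2 lower. By edgeR the floret had 170 higher and 90 lower genes.

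**Figure D4:**
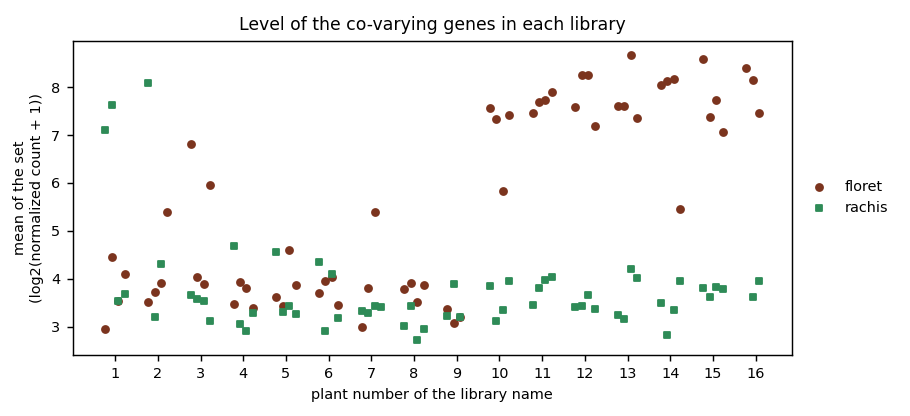
Mean of 26 co-varying genes, as log2(normalized count + 1), in each library by plant number, with floret as circles and rachis as squares. Each number is a seed, temperature and time combination. All 27 floret libraries of plants 10 to 16 lie above 5, against 4 of 34 of plants 1 to 9; of the rachis libraries 0 of 26 and 3 of 34 do.

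Pots to be moved and pots to be kept were compared at 0 h as a check of the starting point. In the floret limma called 0 genes, with 2287 at an unadjusted p under 0.05, and edgeR also called 0. In the rachis the only gene called was TraesCS5B03G1003000.1, on chromosome 5B, higher by a log2 fold change of 1.66 in pots to be moved (SE 0.273, adjusted p = 7.2e-03). The call ended with a stricter filter, with only the compared groups fitted, and without any 1 of the 4 replicate numbers.

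Heads kept at 22 °C changed over the day of sampling. Levels differed between the 4 times in 12243 floret and 14135 rachis genes (5143 to 10002 and 420 to 12923 without single replicate numbers, the 420 without replicate 3). At 24 h, the same hour of the day as 0 h, 1744 genes were higher and 712 lower than at 0 h in the floret, and 4142 were higher and 3919 lower in the rachis, where edgeR gave 4647 and 2885 but TMM factors 3577 and 4605. Taken by seed treatment, 24 h differed from 0 h in 9094 floret and 15308 rachis genes of DMSO heads and in 36 and 8 genes of EBR heads; the difference between the seed treatments was not tested. With the head axis as covariate the counts over time were 921 and 678 and those for 24 h against 0 h were 155 (43 higher, 112 lower, the reverse of the split without it) and 82, where the same plants without it gave 9221 and 14601 over time and 1841 and 5839 for 24 h against 0 h. With only the compared groups fitted, 24 h against 0 h gave 78 and 61 genes, and 7 and 17 for DMSO heads alone, and without single replicate numbers 41 to 4642 and 40 to 11688.

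Floret and rachis were compared in DMSO heads at 22 °C and 0 h. The only gene called was TraesCS4A03G0009200.1, on chromosome 4A, lower in the floret by a log2 fold change of -3.02 (SE 0.51, adjusted p = 2.1e-03), with a mean of 8.62 normalized counts over all libraries. In 3 plants the floret library lay on the rachis side and the rachis library on the floret side of the difference between the tissues. Their floret minus rachis scores were -1.23 (EBR, 22 °C, 16 h, replicate 3), -0.94 (DMSO, 29 °C pots, 0 h, replicate 1) and -0.47 (DMSO, 22 °C, 0 h, replicate 1), against 0.257 to 1.71 in the other plants. Without them 282 genes were higher and 751 lower in the floret. Pairing the tissues by plant (replicate block) gave 9 genes, and leaving out replicate numbers gave 0 to 459.

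**Figure D5:**
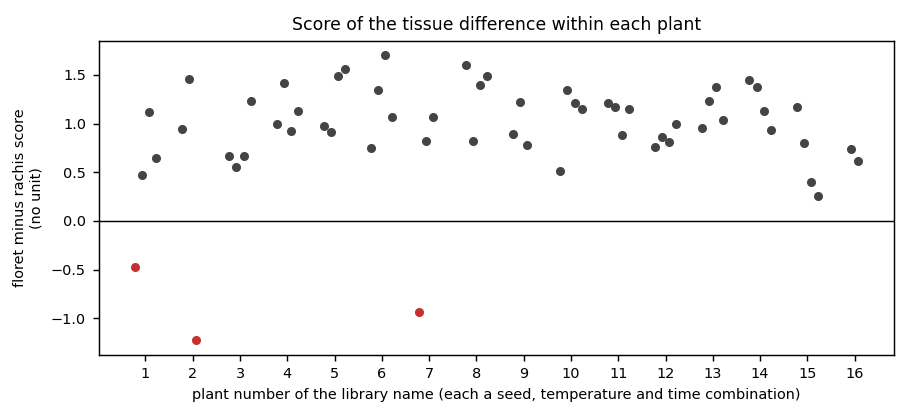
Floret minus rachis score of the tissue difference (no unit) for each plant with both libraries, by plant number; each number is a seed, temperature and time combination and points are plants. The 3 plants under 0 lie at -1.23, -0.94 and -0.47, and all others lie at 0.257 or higher.

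The response to heat, averaged over times and seed treatments, differed between the tissues in 12 genes, larger or less negative in the floret for 9 and in the rachis for 3. Across genes, which are not independent replicates, floret and rachis heat responses correlated with r from 0.534 (8 h, DMSO seed) to 0.773 (8 h, EBR seed). The split of 9 and 3 did not hold: with the tissues paired by plant (replicate block) it was 4 and 4, with a pseudocount of 5 it was 39 and 40, and without replicate 1 it was 16 and 29. The count of 12 was 79 with a pseudocount of 5, 45 with no filter and 1 by edgeR, and it ranged from 0 to 45 without single replicate numbers.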

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

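The tests of the head axis, of exchanged libraries, of plant numbers and of other splits of the samples were chosen only after the results had been seen, and the test of the heat score between seed treatments before.

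Far more genes differed with heat at 24 h after DMSO seed and at 8 h after EBR seed than at the other times, and the 2 groups compared also lay apart on the head axis, by 0.55 and 0.80 in the floret (lowest adjusted exact permutation p over all such contrasts 0.133). Before adjustment each of these 2 floret contrasts had an exact permutation p of 0.0286, the lowest possible with groups of these sizes. The adjusted value thus says little about how far apart the groups lay. Unequal positions of the heads on this axis may account for most of the 8 h count: with the head axis score of the same plant's other tissue as covariate, it fell from 8483 to 1217 in the same floret plants and from 9780 to 828 in the rachis, where 1 group holds 2 libraries. The covariate raised the 8 h count of DMSO heads, from 2056 to 3286 in the floret and from 796 to 1735 in the rachis. For DMSO heads at 24 h the covariate left 11168 genes called against 15380 in the floret and 8958 against 11887 in the rachis. The axis, as far as this single score from the other tissue measures it, is thus not the whole cause. TMM factors gave 14782 floret genes against 14772. This rescaling did not lower the count, though it turned the split into higher and lower genes. What the axis stands for is open, because no marker list could be read. Its score also goes with the number of genes above 0 at equal depth, and heat or EBR could itself move heads along it. A response to heat that depends on the seed treatment, the biological explanation in the design, stays open for both: the EBR by heat interaction at a single time called 8 floret and 5 rachis genes at 8 h and 11235 and 7371 at 24 h, while the heat effect on the heat score was larger in EBR heads by 0.219 and 0.402 at 8 h (adjusted exact permutation p 0.043 and 0.038) and differed by 0.069 and -0.008 at 24 h (0.70 and 0.97).

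In 3 plants both libraries lay on the side of the other tissue. An exchange of the floret and rachis libraries of each plant is a candidate explanation: with their labels exchanged the 3 plants would have scores from 0.47 to 1.23, inside the range of the other plants (0.257 to 1.71). That both libraries lie on the other side is how the 3 were picked and tests nothing. The side of a single library separates less cleanly, since 11 libraries of other plants also lay on the other side (4 floret libraries, all of DMSO heads at 29 °C and 24 h, and 7 rachis libraries), some of them farther over than those of DMSO, 22 °C, 0 h, replicate 1 (-0.419 in the floret and 0.52 in the rachis). Carry-over of some of the other tissue would give scores between 0 and those of the other plants, whereas the highest of the 3 was -0.47, below 0 by more than the SD of the others (0.326). No biological explanation was tested, and no value here shows that an exchange took place.

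Of the 151 floret genes higher with EBR at 0 h, 39 belong to the co-varying set, whose median log2 fold change was 3.43. The set was built from all floret libraries, those at 0 h among them, so this overlap is in part built in. The 0 h comparison sets plant numbers 10 and 12 against 1 and 7. In DMSO heads taken after 0 h the set was higher by 3.405 (SD over genes 0.53) in plants 10 to 16 than in plants 1 to 9. A difference of this size thus also arose without EBR. Each plant number is a single condition, and these DMSO heads were taken at 8 and 16 h in the former plants and at 8 and 24 h in the latter. The value therefore cannot decide whether EBR raised the set at 0 h. A difference that follows the plant number in the floret libraries may be the source: 27 of 27 floret libraries of plants 10 to 16 had a mean above 5 over the 26 genes of the set that also rise and fall together in the rachis, against 4 of 34 in plants 1 to 9. The rachis libraries did not follow the plant number (0 of 26 in plants 10 to 16 and 3 of 34 in plants 1 to 9), which goes against a source that acts on both tissues of a plant alike. In the 3 high rachis libraries the set lay at 7.112, 7.622 and 8.08, and in the floret libraries of the same plants at 2.951, 4.467 and 3.517. The first is from a plant with both libraries on the side of the other tissue, for which an exchange is only a candidate explanation. The tissue scores of the other 2 (0.476 and 0.949) lie inside the range of the other plants, but the former is far below their median of 1.017. The rachis library of the former lay at 0.025, just on the floret side, and that of the latter at -0.476, on the rachis side. For the 112 genes outside the set plant number and EBR cannot be told apart: their median difference with plant number in DMSO heads was 0.071, against 0.67 with EBR at 0 h, but the genes went both ways (67 of 112 higher, SD 0.687). In EBR heads after 0 h it was 0.078 (SD over genes 0.494), below 0.67 by more than this SD. The genes were picked because they were called at 0 h, which can inflate the 0.67, and an SD over genes is not the error of a median. The lower values thus do not decide against plant number. The DMSO arm at 0 h also holds floret libraries of plants with both libraries on the side of the other tissue. Without the 3 plants of this kind 88 genes were called higher and 7 lower with EBR at 0 h, against 151 and 34 with them. These libraries may thus also bear on the calls. Fewer libraries then entered the fit, so their part was not told apart from lost power. In heads of both seed treatments after 0 h, plant number also goes with time and temperature. The labels give no batch, so what the plant number stands for stays open.

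Effects that differed between groups by a test of the difference were the EBR by heat interaction in the floret (11896 genes) and the rachis (9262 genes), the tissue by heat interaction (12 genes), and the heat score, whose heat effect was larger in EBR than in DMSO heads by 0.185 in the floret and 0.196 in the rachis. With the head axis as covariate the EBR by heat counts were 2773 and 1275, against 12410 and 7608 in the same plants without it. The tissue by heat count was 1 by edgeR. For the EBR by heat interaction in the rachis chance cannot be excluded, since 5 of 100 splits were as large.

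Other splits of the same libraries were called in the same way as the real groups. A share of splits under 0.05 was taken as low. The shares were not adjusted for the number of comparisons, so a low share does not by itself exclude chance. The lowest share possible, the real split alone of 35, held in the floret for heat after DMSO seed at 8 h (1678 genes, highest other split 240), 16 h (1953, highest other 19) and 24 h (14772, highest other 9973) and after EBR seed at 8 h (11564, highest other 6865) and 24 h (1877, highest other 380). In the rachis it held for heat after DMSO seed at 16 h (809, highest other 182) and 24 h (11798, highest other 10153) and after EBR seed at 24 h (1016, highest other 1). Among 100 drawn splits the real one alone was as large for EBR in any condition in floret (22557, highest other 19181) and rachis (20763, highest other 15259), for EBR at 0 h in the floret (185, highest other 180) and for time at 22 °C in floret (12243, highest other 9851) and rachis (14135, highest other 13013). The share was also under 0.05 for the EBR by heat interaction in the floret (11896, with 4 of 100 splits as large, highest other 17010), EBR at 22 °C in the floret (400, 3 of 100, highest other 7102), 24 h against 0 h in the floret (2456, 4 of 100, highest other 5195), EBR at 0 h in the rachis (7, 4 of 100, highest other 1064) and the tissue by heat interaction (12, 2 of 100, highest other 20, with the tissues of a plant kept together). In each of these another split called more genes than the real one, so chance is not excluded for them. For EBR at 22 °C in the floret and EBR at 0 h in the rachis the low share says little about the seed treatment, since another split called many times the real count.

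The share was 0.05 or more, and chance cannot be excluded, for heat after EBR seed at 16 h in the floret (2494, with 2 of 35 splits as large, highest other 2906), heat after DMSO seed at 8 h in the rachis (754, 2 of 35, highest other 2448), the EBR by heat interaction in the rachis (9262, 5 of 100, highest other 20657), EBR at 29 °C in floret (1608, 6 of 100, highest other 20671) and rachis (2124, 7 of 100, highest other 19621), EBR at 22 °C in the rachis (1, 13 of 100, highest other 3052), pots at 0 h in the rachis (1, 11 of 100, highest other 591), 24 h against 0 h in the rachis (8061, 6 of 100, highest other 13416) and floret against rachis (1, 10 of 35, highest other 457, which is also the highest of the 8 splits that part the tissues of every plant). The splits of floret against rachis used the fit without pairing by plant. That count was 9 with the tissues paired by plant and 1033 without the 3 plants on the other tissue side. For pots at 0 h in the floret the real count of 0 by limma (2287 genes at an unadjusted p under 0.05, and 0 by edgeR) makes all 100 of 100 splits as large, so the splits say nothing there (highest other 1). Splits called several times the real count for EBR at 22 °C and 29 °C, for EBR and pots at 0 h in the rachis, for heat at 8 h after DMSO seed in the rachis and for the tissues. A structure of the samples besides the groups may give such counts, but their source was not tested. For EBR at 29 °C the real groups may give them too. There EBR minus DMSO on the floret head axis was 0.423 at 8 h, 0.601 at 16 h and -1.299 at 24 h. Differences of opposite sign can cancel in the real mean over times and not in a relabelled one. For heat at 16 h after EBR seed in the rachis the 10 splits are too few (512, highest other 3), and heat at 8 h after EBR seed in the rachis was not tested in this way, since a group holds 2 libraries.

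Of 360 groups of 4 libraries tested, 26 held a library far from the other 3, where chance gives about 1 in 20. In 6 of the 26 all values of the gene were under 3 normalized counts, where single reads decide; the other 20 were among 340 groups. Some gene IDs were left out of the text because of such libraries, so these numbers cannot be set against chance. The rachis library of DMSO 22 °C 8 h replicate 4 had 39916 genes above 0 at equal depth, against 41382 to 41650. The floret library of DMSO 22 °C 24 h replicate 2 had a head axis score of -0.304 against 0.594 to 0.755 and a heat score of -0.294 against 0.029 to 0.042. The floret library of EBR 29 °C pots 0 h replicate 3 had a head axis score of 0.152 against -0.224 to -0.165. The mean of the 26 genes of the co-varying set was 5.461 in floret DMSO 22 °C 16 h replicate 4 (others 8.04 to 8.17), 5.828 in floret EBR 22 °C 0 h replicate 3 (others 7.34 to 7.56) and 4.566 in rachis EBR 22 °C 24 h replicate 1 (others 3.28 to 3.43).

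Single genes gave the rest, as normalized counts. TraesCS1B03G0819300.1 had 306 in rachis DMSO 22 °C 0 h replicate 3, against 834 to 889. TraesCS2D03G0784200.1 had 1.67 in floret DMSO 29 °C 16 h replicate 1, 1.76 in floret EBR 29 °C 24 h replicate 1, 1.2 in rachis EBR 22 °C 0 h replicate 1, 1.95 in rachis EBR 22 °C 24 h replicate 4 and 1.03 in rachis EBR 29 °C 24 h replicate 4, where the other libraries were at 0, and it was listed at 0 in floret EBR 22 °C 0 h replicate 1, where the others had 0.722 to 0.797. TraesCS2B03G0442100.1 had 419 in rachis EBR 29 °C pots 0 h replicate 1, against 3130 to 3500. TraesCS2D03G0341300.1 had 193 in floret DMSO 29 °C 16 h replicate 1, against 50.1 to 57.4. TraesCS5A03G0211100.1 had 1850 in rachis DMSO 29 °C 16 h replicate 4, against 5740 to 6030, and 3510 in rachis DMSO 29 °C 24 h replicate 1, against 2360 to 2460. TraesCS3B03G1122300.1 had 22 in floret EBR 29 °C 8 h replicate 4, against 33.3 to 35. TraesCS5B03G1003000.1 had 45 in floret DMSO 22 °C 0 h replicate 1 (others 5.85 to 8.18), 10.5 in floret DMSO 22 °C 16 h replicate 4 (others 84.3 to 90.2), 108 in floret DMSO 29 °C 24 h replicate 1 (others 53.8 to 60.8), 20.4 in rachis DMSO 22 °C 24 h replicate 3 (others 32.3 to 33.5) and 54.4 in rachis DMSO 29 °C pots 0 h replicate 1 (others 91.8 to 96.2). TraesCS4A03G0009200.1 had 6.68 in floret DMSO 22 °C 16 h replicate 2, against 11.3 to 12, and 31.4 in rachis EBR 29 °C 8 h replicate 1, against 2.03 to 5.87.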

How the results depend on the processing

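The settings without the 3 plants, without the co-varying set and with the head axis covariate were chosen only after the results had been seen; the others were planned. Of the 30 counts compared, TMM rescaling moved 0 by over 1.5 times, the pseudocounts of 0.5 and 5 moved 2 and 1, no filter and the stricter filter 5 each, edgeR 4, the replicate block 1, the fit of only the compared groups 19, leaving out replicate number 1, 2, 3 or 4 19, 22, 23 and 15, leaving out the 3 plants 8, and the covariate 21 of 28. The covariate fit also holds only plants with both libraries and without the 3 plants; against the same plants without the covariate it moved 18 of 28. No named gene turned its direction. Except where fewer libraries or genes entered the fit, the cause was not tested. In libraries simulated once with the spread of these data, limma called 12% of 200 genes changed 1.5-fold in the floret at 0.5 times the depth, 12% at the depth as it is, 11% at 2 times and 15.5% at 4 times, and 0.5%, 0.5%, 2% and 6.5% in the rachis. With genes changed 2- and 4-fold simulated beside them the shares of 67 such genes were 17.9%, 20.9%, 13.4% and 28.4% in the floret and 8.96%, 8.96%, 8.96% and 16.4% in the rachis, and another draw at the depth as it is gave 16.4% and 17.9%. The shares thus vary with the draw and the other genes. All changed genes had a mean of at least 50, and genes were simulated independently, without the head axis. Among such genes 2 times the depth added few or none. What depth would add for genes of lower level was not simulated.

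With a pseudocount of 0.5 EBR at 22 °C in the rachis gave 2 genes and the tissue by heat interaction 5, and with a pseudocount of 5 the latter gave 79. With no filter EBR at 22 °C gave 94 in the floret and 10 in the rachis, pots at 0 h in the rachis 2, floret against rachis 2 and the tissue by heat interaction 45. With the stricter filter EBR at 29 °C in the floret gave 850 and the tissue by heat interaction 2, and limma called 0 for EBR at 22C, rachis (7302 genes at an unadjusted p under 0.05; edgeR with the usual filter 1), pots at 0 h, rachis (1575; edgeR 3) and floret vs rachis, DMSO 22C 0 h (1837; edgeR 2). By edgeR EBR at 29 °C in the floret gave 804, pots at 0 h in the rachis 3, floret against rachis 2 and the tissue by heat interaction 1. With the replicate block, which for the 2 tests between tissues is the plant, floret against rachis gave 9; the block changed no other count by over 1.5 times.

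With only the compared groups fitted, and so fewer libraries, the floret gave 531 genes for heat at 8 h after DMSO seed, 60 and 1116 for heat at 16 h and 24 h after EBR seed and 78 for 24 h against 0 h. The rachis gave 36, 219 and 1953 for heat after DMSO seed, 5578 at 8 h and 634 at 24 h after EBR seed, 5671 for the EBR by heat interaction, rachis, 8615 for time at 22C, rachis, and 61 for 24 h against 0 h; the tissue by heat interaction gave 1. Here limma called 0 for EBR at 22C, floret (6329 at an unadjusted p under 0.05; edgeR on all groups 461), heat at 16 h, EBR seed, rachis (4047; edgeR 482), EBR at 0 h, rachis (2844; edgeR 7), EBR at 22C, rachis (4791; edgeR 1), pots at 0 h, rachis (3195; edgeR 3) and floret vs rachis, DMSO 22C 0 h (1841; edgeR 2).

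Without the 3 plants the floret gave 95 genes for EBR at 0 h, 2657 for EBR at 22 °C and 2454 for EBR at 29 °C, the rachis 322 for heat at 16 h after EBR seed, 3 for EBR at 0 h, 2 for EBR at 22 °C and 3 for pots at 0 h, and floret against rachis gave 1033. Without the co-varying set EBR at 0 h in the floret gave 98. With the covariate the floret gave 3286 for heat at 8 h after DMSO seed, 1217 and 3156 at 8 h and 24 h after EBR seed, 2773 for the EBR by heat interaction, floret, 7512 for EBR in any condition, floret, 3845 for EBR at 29 °C, 921 for time at 22C, floret, and 155 for 24 h against 0 h; the rachis gave 1735 for heat at 8 h after DMSO seed, 828, 855 and 1565 after EBR seed, 1275 for the EBR by heat interaction, rachis, 3650 for EBR in any condition, rachis, 2 for EBR at 0 h, 3986 for EBR at 29 °C, 678 for time at 22C, rachis, and 82 for 24 h against 0 h. With the covariate limma called 0 for EBR at 22C, floret (3689 at an unadjusted p under 0.05; edgeR on all libraries without it 461; limma in the same plants without it 149), EBR at 22C, rachis (1975; edgeR 1; same plants 2) and pots at 0 h, rachis (2645; edgeR 3; same plants 0). The same plants without it also gave 2 for EBR at 0 h in the rachis, so this count and that for pots at 0 h in the rachis moved with the plants and not with the covariate.

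Leaving out each replicate number, and so fewer libraries, gave these lowest and highest counts in the floret: heat after DMSO seed 510 to 1299, 253 to 1593 and 6923 to 15215 at 8, 16 and 24 h, and after EBR seed 5914 to 10864, 591 to 1746 and 581 to 1176. EBR by heat ranged from 1551 to 11410, EBR in any condition from 16728 to 19730, EBR at 0 h from 73 to 209, at 22 °C from 0 to 355 and at 29 °C from 290 to 3813, time from 5143 to 10002, and 24 h against 0 h from 41 to 4642. In the rachis heat after DMSO seed ranged from 201 to 510, 142 to 755 and 3775 to 14022, and after EBR seed from 242 to 11684, 57 to 811 and 192 to 680. EBR by heat ranged from 348 to 12629, EBR in any condition from 11595 to 19708, EBR at 0 h from 0 to 7, at 22 °C from 0 to 65 and at 29 °C from 278 to 1411, pots at 0 h from 0 to 1, time from 420 to 12923, and 24 h against 0 h from 40 to 11688. Floret against rachis ranged from 0 to 459 and the tissue by heat interaction from 0 to 45. The lowest count came without replicate 2 or 3 in most of these. Leaving out a replicate can leave an arm with 1 library, which is then assumed to vary like the other groups.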

Other observations

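The subgenome test and the test of the heat score between seed treatments were chosen before their results were seen; the other settings of the heat score were chosen only after.

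The overlap of heat comparisons at different times was uneven. At 8 h and 16 h after DMSO seed in the floret 228 genes were higher in both (18 expected by chance) and 195 lower in both (24.9 expected), but at 16 h and 24 h 205 were higher in both (196.5 expected) and 157 lower in both (178.5 expected). A difference of the heat effect between times was not tested. Across genes, which are not independent replicates, the heat effects of 2 comparisons in a tissue correlated with r between -0.434 (16 h after DMSO seed and 8 h after EBR seed, floret) and 0.639 (8 h and 16 h after EBR seed, rachis). The 2 comparisons of the former pair were shifted in opposite directions on the head axis (-0.397 and 0.804), which held 48.48% and 69.21% of their squared fold changes. Of the genes called in both, 547 of 642 went the same way in the former pair and 311 of 315 in the latter, but only 362 of 655 at 16 h and 24 h after DMSO seed in the floret. At 8 h the seed treatments shared 1216 floret genes, all 1216 in the same direction. At 24 h they shared 754, of which 573 went the same way. Genes defined by all 3 times after EBR seed were checked in DMSO heads at 24 h in the floret, where 168 of the 178 higher genes and 202 of the 238 lower genes kept their sign.

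EBR against DMSO at single times in the floret gave 63, 9, 50 and 4014 genes at 22 °C and 0, 8, 16 and 24 h, and 173, 49, 47 and 25075 genes in the pots for 29 °C. The count for EBR vs DMSO at 22C, 24 h, floret rested on the shared spread: with only the compared groups fitted limma called 0 (6465 at an unadjusted p under 0.05), while edgeR on all groups called 4090, and with the head axis as covariate it was 308.

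A first hypothesis was that EBR given to the seed changes the size of the heat response of the genes that respond at every time. Scored on genes chosen in the other tissue, the heat effect averaged over 3 times was 1.60 in EBR and 1.41 in DMSO heads in the floret, a difference of 0.185 (permutation p = 0.0045, adjusted 0.036 over 8 tests), and 1.46 against 1.26 in the rachis, a difference of 0.196 (permutation p = 0.021, adjusted 0.043). By time the difference was 0.219, 0.268 and 0.069 at 8, 16 and 24 h in the floret (adjusted exact permutation p 0.043, 0.043 and 0.70) and 0.402, 0.195 and -0.008 in the rachis (0.038, 0.11 and 0.97), where the 22 °C group of EBR heads at 8 h held 2 libraries. With other gene choices or the head axis as covariate it lay between 0.141 and 0.259, with permutation p from 3e-05 to 0.03. These values are consistent with a modestly stronger response after EBR; whether the difference changes with time was not tested, both tissues come from the same heads, and the hypothesis was tested on the data that raised it.

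A second hypothesis was that the A, B and D subgenomes of wheat respond unequally to heat. The tests used a part of the 38320 floret genes, 10107, 10063 and 10164 of A, B and D. Of these, 1.91%, 2.02% and 2.09% were called higher at 8 h after DMSO seed. Of 24 tests of heat comparisons by direction and tissue 0 had an adjusted chi-square p under 0.05, the lowest being 0.64 (lowest unadjusted p 0.12). Chi-square tests over genes treat genes as independent, and unequal response was not detectable here.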
